A study of Homo sapiens with 15 samples.

How the data were processed

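Libraries of PSN-1, an established human PDAC line, were grouped from the titles in the labels: siControl, siMondoA and siMLX in the first experiment and DMSO and SBI-477 in the second, 3 libraries each and 15 in all. Per the labels' protocols, cells were grown in RPMI with 10% fetal bovine serum and treated for 72 hours, RNA was extracted with Direct-zol kits, 500 ng entered Kapa library preparation, and paired 25-base reads were sequenced on an Illumina HiSeq instrument. Whether the kit marked strand or selected polyadenylated RNA is not given in the sources used here. Per the submitters' processing notes, the tools were bcl2fastq 1.8.4, TopHat2 2.1.0, HTSeq 0.6.1 and edgeR (no version), and both hg38 and mm10 are named as builds; human gene symbols are used in the tables. Reads of 25 bases from near-identical genes cannot be placed apart, so values of ribosomal protein genes, CXCL1 and CXCL3, CST1 and CST4, and UGT1A7 are uncertain.

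The authors deposited 1 table per experiment, each with 26485 gene symbols and a raw count per gene and library, per the file headers; the counts are whole numbers with unequal totals. No library of another study was among the columns and every entry named a gene. The same deposited tables hold the authors' own comparisons, per the file headers: a log2 fold change and a p-value with its adjusted p-value. The authors' tool for these columns is not stated; their names are those DESeq2 writes. They were used to compare with the counts, over genes with a mean normalized count above 20 in the DESeq2 fit run here, and any value taken from them is named as such. DESeq2 1.42.0 with a replicate term gave back the siRNA columns to a median absolute difference of 2.27e-13 for siMondoA (11935 genes) and 2.21e-13 for siMLX (11952 genes) with the labels as given. The drug columns were matched only with DMSO replicate 2 and SBI-477 replicate 2 exchanged, among 9 exchanges of a pair of libraries between the groups. Libraries are nevertheless named by their labels, and the drug comparison is also given for replicates 1 and 3.

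Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr, libraries were scaled by TMM, and edgeR's quasi-likelihood test was run without a replicate term, with the 9 siRNA libraries in 1 fit and the 6 drug libraries in another. The difference between the SBI-477 and siMondoA effects was an interaction term in 1 fit of both experiments. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. CPM were computed with TMM factors and log2 CPM with a prior count of 2. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. The design, the settings to vary (apart from those named below as added), the gene lists and the rule for named genes were fixed before the data were examined.

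The 30 gene lists cover the MYC network, MondoA and ChREBP targets, stress and growth programs, metabolism, inflammation, cell death, PDAC states and markers of other cell types, and the result of each after siMondoA is given in the report or under the other observations. They hold 614 distinct genes, of which 584 matched by symbol and 28 by an older symbol, and 2 did not match. Lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison; camera with an estimated correlation and fry were the alternatives. The sets of genes highest and lowest after siMondoA were tested in the drug libraries in the same way, adjusted over these 2 sets, an adjustment added after the values were seen. The preset value ignores how strongly members vary together, and no list passed with the estimated correlation. Gene positions come from GENCODE v29 on GRCh38, used for position and exon length only.

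Named genes followed a fixed rule: the MYC network; a set of sentinel genes of MondoA activity, the stress response and MYC; per comparison the 8 largest rises and falls with an adjusted p under 0.05, a mean of at least 4 CPM over the libraries compared and no overlap between the groups' libraries; up to 4 members per list with the smallest adjusted p; and up to 4 genes per other set. All of the 8 largest rises and falls are named for each comparison with calls. Which of the other candidates appear was decided when writing, after values were seen, and some of them are not reported here. Named outside the rule, after their values were seen, are PCK1 and DMBT1 after siMLX, CCL20 and PCK1 in the difference between SBI-477 and siMondoA effects, and PCK1 in the drug libraries as labelled.

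Floors were computed as 3 counts over the library total, 0.204 to 0.267 CPM in siRNA libraries and 0.0984 to 0.129 CPM in drug libraries, and cover counting error only. Within groups, log2 CPM correlated at 0.991 to 0.994 in siControl, 0.974 to 0.989 in siMondoA, 0.974 to 0.993 in siMLX, 0.976 to 0.995 in DMSO and 0.988 to 0.997 in SBI-477. The lowest chi-square per degree of freedom between replicates was 8.26, so no pair of libraries of the same group matched within sampling noise; pairs across groups were not tested. Replicate numbers were checked for pairing by correlating the deviations of same-numbered libraries from their group means. For siMLX and siControl the correlations were 0.27, 0.19 and 0.36, all above 0.1, so the replicate block is given beside that comparison where it changes a call. For the others at least 1 pair was below that bound.

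The tests were tried on simulated counts with 50 changed genes at each of 4 fold sizes. For siMondoA against siControl (12877 genes) edgeR recovered 86% of genes lowered by 2 on the log2 scale, 74% of those lowered by 1, 68% of those raised by 1 and 98% of those raised by 2, with 5.78% false calls. For SBI-477 against DMSO (13886 genes) these were 90%, 58%, 68% and 100%, with 5.95% false calls, and for the difference of effects (13385 genes) 76%, 28%, 34% and 86%, with 7.44%. DESeq2 had 12.4% and 14.1% false calls in the first 2 settings. In the first 2 settings camera, camera with an estimated correlation and fry each found the changed list among 30 lists of 30 genes and passed no random list. The simulated genes were drawn independently, so this cannot show how often camera passes lists whose members vary together.

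Alternatives were DESeq2 size factors, library totals, no filter, a filter of 1 CPM in 3 libraries, limma-voom, DESeq2, the replicate block, only the 6 libraries compared, and leaving out each library in turn. Added after seeing the data were the 4 drug libraries of replicates 1 and 3, the exchanged labels, all settings varied within replicates 1 and 3, lists with only the 6 libraries compared, overlaps without siMLX replicate 2, and simulated overlaps with the controls drawn too. So were leaving out libraries for the difference of effects, and size factors, the block and left-out libraries for the siMondoA gene sets. Settings for deposited normalized values were not run, since counts were deposited. Single-exon and isoform changes, and reads on either strand, were not analysed here.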

Results

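PSN-1 is an established human cell line from pancreatic ductal adenocarcinoma (PDAC). Gene-level RNA-seq counts of 15 PSN-1 libraries were analysed, from a pair of experiments of 72 hours each. In the first, cells were transfected with a control siRNA (siControl), with siRNA against MondoA (siMondoA; gene symbol MLXIP) or with siRNA against its partner MLX (siMLX), with 3 libraries per group. MondoA is a glucose-sensing transcription factor that binds DNA together with MLX and belongs to the same network of dimerising factors as MYC. In the second, cells received the vehicle DMSO or SBI-477, which the labels describe as a MondoA inhibitor, again with 3 libraries per group. Replicates 1, 2 and 3 held 11257452, 12876546 and 14731691 counts in siControl, 12405037, 13329700 and 12680657 in siMondoA and 11227343, 13134359 and 13166441 in siMLX. The drug libraries were deeper, with 29177289, 24282047 and 30480362 counts in DMSO and 29585149, 23452515 and 23315440 in SBI-477. Levels are CPM after TMM scaling, given as mean ± SD over 3 libraries, and fold changes are on the log2 scale with their standard error. A gene is said to have risen or fallen where edgeR's quasi-likelihood test gave a Benjamini-Hochberg adjusted p under 0.05. Nothing in the labels says that replicates were separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

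The targeted transcripts were lower in each library labelled with their siRNA. MLXIP (chromosome 12, 122078722 to 122147347, plus strand; GENCODE v29 on GRCh38 for all positions here) was at 83.6, 65.8 and 88.7 CPM in siControl and at 22.6, 23.4 and 15.7 CPM in siMondoA (log2 fold change -1.95 ± 0.17, edgeR adjusted p = 0.000118). It was at 65.7 ± 3.05 CPM in siMLX (-0.27 ± 0.16, edgeR adjusted p = 0.316). MLX (chromosome 17, 42567068 to 42573239, plus strand) was at 53.4, 58.8 and 53 CPM in siControl and at 11.9, 7.15 and 7.70 CPM in siMLX (-2.63 ± 0.18, edgeR adjusted p = 8.21e-05), against 71.1 ± 3.47 CPM in siMondoA (0.37 ± 0.16, edgeR adjusted p = 0.114). A drug has no transcript of its own to check, and MLXIP was at 77.9 ± 2.97 CPM in DMSO and 73.2 ± 7.62 CPM in SBI-477.

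**Figure D1:**
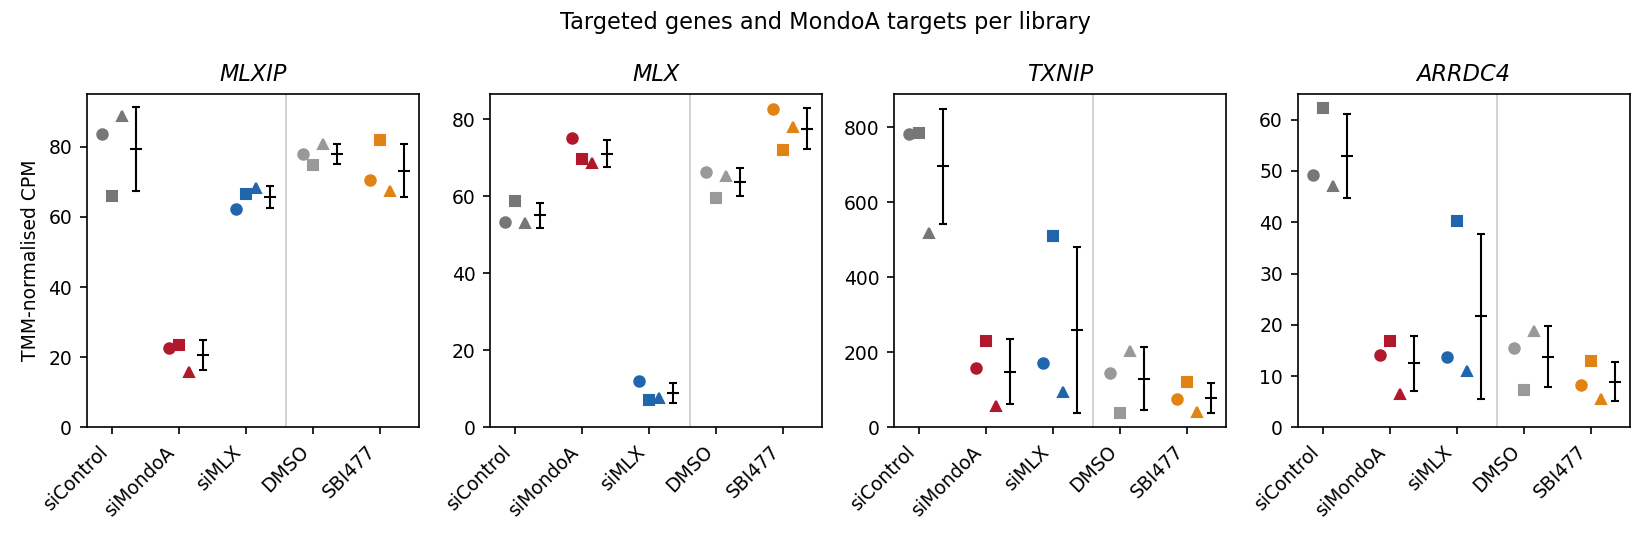
Normalised expression in CPM (vertical axis) of MLXIP, MLX, TXNIP and ARRDC4 in each library of the 5 groups, with marker shape giving the replicate number and bars giving the mean ± SD of 3 libraries. MLXIP lies between 15.7 and 23.4 CPM in siMondoA, MLX between 7.15 and 11.9 CPM in siMLX, and TXNIP in siMLX replicate 2 at 511 CPM.

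The first comparison, siMondoA against siControl, asks which transcripts change with the siRNA against MondoA in these cells. The samples hold no rescue, so effects of loss of MondoA and of the siRNA itself cannot be told apart. TXNIP (chromosome 1, 145992435 to 145996600, minus strand), an arrestin-like inhibitor of thioredoxin and glucose uptake and the best known MondoA target, fell from 696 ± 153 to 149 ± 86.7 CPM (-2.23 ± 0.60, edgeR adjusted p = 0.0221). Its relative ARRDC4 (chromosome 15, 97960698 to 97973838, plus strand) fell from 52.9 ± 8.21 to 12.5 ± 5.34 CPM (-2.08 ± 0.47, edgeR adjusted p = 0.0105). Genes of the integrated stress response (ISR), the program that the transcription factor ATF4 drives when translation initiation is restrained, rose: ATF4 itself went from 277 ± 37.2 to 677 ± 141 CPM and 37 of 43 listed members rose. So did 13 of 16 NF-kB targets and cytokines, 13 of 17 immediate early genes and 13 of 28 mitotic genes, while 24 of 71 cytosolic ribosomal protein genes fell. Each of these lists passed by camera at the preset correlation, but had an adjusted p = 0.61 with an estimated correlation. In all, 1849 genes rose and 1683 fell of 13001 tested, 575 and 598 of them at least 2-fold.

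Among ISR genes, CHAC1 (chromosome 15, 40952962 to 40956519, plus strand), which degrades glutathione, rose from 0.941 ± 0.393 to 86.5 ± 17.5 CPM (6.51 ± 1.57, edgeR adjusted p = 0.0142). ASNS (chromosome 7, 97852118 to 97872542, minus strand), the asparagine synthetase, rose from 24.6 ± 4.25 to 279.7 ± 189.6 CPM (3.51 ± 1.06, edgeR adjusted p = 0.0332). The stress transcription factor DDIT3 rose by 3.58 ± 0.81, the pseudokinase TRIB3 by 3.43 ± 0.89, the mTORC1 inhibitor SESN2 by 3.44 ± 0.77 and the serine synthesis enzyme PSAT1 by 2.23 ± 0.62 (edgeR adjusted p 0.0112, 0.0187, 0.0106 and 0.0241), and ATF4 by 1.29 ± 0.28 (0.00948). The 4 members with the smallest edgeR adjusted p were CEBPB (1.51 ± 0.22, 0.00161), SLC3A2, the heavy chain of amino acid exchangers (2.19 ± 0.39, 0.00398), VEGFA (2.54 ± 0.46, 0.00411) and DDIT4 (1.76 ± 0.34, 0.00575). No member fell; adjusted over the list alone 41 rose, the median was 2.09, and camera gave an adjusted p of 1.23e-11, against an adjusted p = 0.61 with an estimated correlation. The list's median log2 level above the siControl mean was 1.19, 2.68 and 1.96 in siMondoA replicates 1, 2 and 3. Without siControl replicates 1, 2 and 3 the count of members that rose was 12, 11 and 16. Without siMondoA replicates 1, 2 and 3 the count was 41, 19 and 20.

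**Figure D2:**
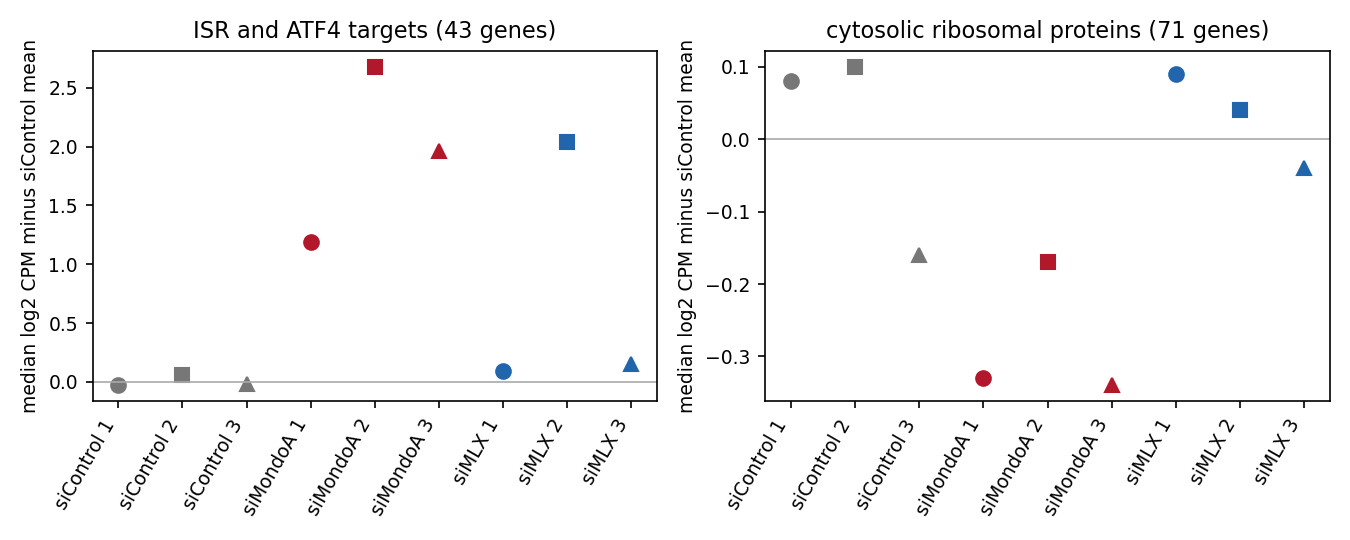
Median log2 CPM of 43 integrated stress response genes and of 71 cytosolic ribosomal protein genes in each siRNA library, relative to the mean of the siControl libraries (vertical axis, log2). For the stress list siMondoA replicates lie at 1.19, 2.68 and 1.96 and siMLX replicates at 0.09, 2.04 and 0.15. For the ribosomal list siMondoA replicates lie at -0.33, -0.17 and -0.34 and siControl replicates at 0.08, 0.1 and -0.16.

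Of 16 NF-kB targets and cytokines tested, 13 rose and none fell (14 and 1 adjusted over the list alone; camera adjusted p = 1.05e-06, but adjusted p = 0.61 with an estimated correlation). The chemokine CCL20 rose from 0.291 ± 0.134 to 28.9 ± 12.5 CPM (6.64 ± 1.08, edgeR adjusted p = 0.00272), the cytokine IL1A from 2.28 ± 0.536 to 90.3 ± 48.4 CPM (5.31 ± 0.90, 0.00316) and the apoptosis inhibitor BIRC3 from 9.34 ± 2.12 to 41.5 ± 10.7 CPM (2.16 ± 0.26, 0.000609). CXCL1, near-identical in sequence to other chemokines and so uncertain, rose by 1.90 ± 0.33 (edgeR adjusted p = 0.00381). Of 17 immediate early genes 13 rose (13 adjusted over the list alone), among them the AP-1 subunit FOSL1 (2.01 ± 0.27, edgeR adjusted p = 0.0012) and the growth factor response gene EGR1 (2.84 ± 0.53, 0.005). The list's camera adjusted p was 4.42e-05 (adjusted p = 0.61 with an estimated correlation), and 7, 7 and 7 members rose without siControl replicate 1, siControl replicate 2 and siMondoA replicate 3. Without siControl replicate 3, siMondoA replicate 1 and siMondoA replicate 2 the count was 9, 13 and 10. Of 14 mesenchymal and basal PDAC genes 6 rose (8 adjusted over the list alone). The camera adjusted p was 0.0328, or 0.0587 without siControl replicate 3 (adjusted p = 0.61 with an estimated correlation).

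Mitotic genes rose by less: 13 of 28 tested (16 up and 1 down adjusted over the list alone; median 0.40, camera adjusted p = 0.000156, but adjusted p = 0.61 with an estimated correlation). The mitotic kinase AURKA rose from 154 ± 8.49 to 312 ± 31.9 CPM (1.01 ± 0.11, edgeR adjusted p = 0.000462), its spindle activator TPX2 by 1.05 ± 0.12 (0.000594) and the centromere histone CENPA by 0.91 ± 0.14 (0.00227). The mitotic count was 7 and 6 without siControl replicates 1 and 2, 12 without siControl replicate 3, and 9, 10 and 10 without siMondoA replicates 1, 2 and 3. Of 71 cytosolic ribosomal protein genes, 24 fell and none rose (32 fell adjusted over the list alone), with a median of -0.29 and a camera adjusted p of 1.16e-08 (adjusted p = 0.61 with an estimated correlation). RPL34 fell from 553 ± 55.4 to 323 ± 12.6 CPM (-0.78 ± 0.13, edgeR adjusted p = 0.00271), RPL11 by -0.67 ± 0.12 (0.00395) and RPL23 by -0.64 ± 0.11 (0.00395); these genes share sequence with many processed pseudogenes, so single values are uncertain. Without siControl replicates 1 and 2 and siMondoA replicates 1 and 3 the ribosomal count was 4, 4, 9 and 4. Without siControl replicate 3 and siMondoA replicate 2 the ribosomal count was 32 and 29. Over these fits the list's median was -0.25 to -0.37. Relative to the siControl mean, the ribosomal median was 0.08, 0.1 and -0.16 in siControl replicates 1, 2 and 3. In siMondoA replicates 1, 2 and 3 it was -0.33, -0.17 and -0.34, so siControl replicate 3 was level with siMondoA replicate 2. Of 40 oxidative phosphorylation genes 7 fell and 2 rose (camera adjusted p = 0.0519), with NDUFA2 (-1.22 ± 0.15, edgeR adjusted p = 0.000651) and COX5B (-0.68 ± 0.11, 0.00294) among those that fell. Both are subunits of the respiratory chain.

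The MYC network itself moved in both directions. MYC fell from 635 ± 55.5 to 489 ± 17.4 CPM (-0.38 ± 0.12, edgeR adjusted p = 0.0385), a call lost without each of the 6 libraries in turn (0.0572 to 0.128). Its antagonists MXD4 and MXD1 went in opposite directions, MXD4 falling by -1.27 ± 0.20 (edgeR adjusted p = 0.00253) and MXD1 rising by 1.60 ± 0.45 (0.0258, but 0.0641 to 0.0906 without any library but siMondoA replicate 1). MLXIPL, the MondoA paralog ChREBP, rose by 1.79 ± 0.59 (edgeR adjusted p = 0.0451, but 0.0518 to 0.238 without any library but siMondoA replicate 1). With MLXIP, this made 2 of 12 listed members up and 3 down (2 and 5 adjusted over the list alone; camera adjusted p = 0.264). Of 18 listed targets of MondoA and ChREBP 6 rose and 6 fell (6 and 7 adjusted over the list alone; camera adjusted p = 0.336): TXNIP, ARRDC4 and the cell cycle repressor HBP1 (-0.92 ± 0.17, edgeR adjusted p = 0.00478) fell, while hexokinase HK2 (0.62 ± 0.13, 0.00945) and TRIB3 rose. The median of that list was -0.44 and its mean 0.39, so they differ in sign. Of 5 arrestin domain genes 3 fell, TXNIP, ARRDC4 and ARRDC3 (-0.86 ± 0.16, edgeR adjusted p = 0.00499), with a camera adjusted p of 0.088. Of the polyamine enzyme ODC1 (0.38 ± 0.18, edgeR adjusted p = 0.133) and the sterol synthesis enzyme HMGCS1 (-0.67 ± 0.48, 0.318) neither passed.

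Among called genes with a mean of at least 4 CPM over the libraries compared and no overlap between the groups, the steepest fall was that of PCK1 (chromosome 20, 57561080 to 57568112, plus strand), the cytosolic enzyme that commits oxaloacetate to gluconeogenesis, from 105 ± 37.6 to 2.63 ± 1.63 CPM (-5.31 ± 0.49, edgeR adjusted p = 0.00017). The next falls were those of the collagen chain COL1A2 (-3.91 ± 0.56), the mucosal glycoprotein DMBT1 (-3.28 ± 0.22), the integrin chain ITGA10 (-3.24 ± 0.28), FAM105A (-3.09 ± 0.38), cyclooxygenase PTGS1 (-2.93 ± 0.25) and the near-identical cystatins CST1 (-2.95 ± 0.33) and CST4 (-3.26 ± 0.42), whose reads may be shared. Apart from OLR1, S100A8 and SERPINB2, given next, rises were led by INHBE, an activin subunit (7.02 ± 1.91, edgeR adjusted p = 0.0224), CCL20, CHAC1, IL1A and the adaptor GAB2 (5.19 ± 0.72, 0.00143). OLR1, S100A8 and SERPINB2 were below the counting floor in siControl, at 0.0517, 0.125 and 0.129 CPM, and reached 12, 11.6 and 10.5 CPM. Their fold changes are therefore uncertain.

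Of 71 genes named for siMondoA 68 were called. The number of genes called in all was 1878, 1745 and 2245 without siControl replicates 1, 2 and 3 and 2276 and 1944 without siMondoA replicates 2 and 3, and 56 of the 68 named calls were made without each library in turn. The others lost it without siControl replicate 1 (11 genes), 2 (12) or 3 (10) or siMondoA replicate 1 (1), 2 (7) or 3 (7), at edgeR adjusted p values up to 0.238. TXNIP was at 0.0626, 0.0672 and 0.0663 without siControl replicates 1 and 2 and siMondoA replicate 3, and ASNS at 0.071 to 0.108 without any library but siMondoA replicate 1. CHAC1 was at 0.0579, 0.057 and 0.0558 and TRIB3 at 0.0696, 0.0702 and 0.0619 without siControl replicates 1, 2 and 3. The remaining ones were MYC, MXD1, MLXIPL, PSAT1, BBC3, INHBE, PMAIP1 and KDR. The spread in this fit was estimated over the siMLX libraries too. There the ISR list stood high in replicate 2 alone (median 2.04, against 0.09 and 0.15 in replicates 1 and 3). With only the 6 libraries compared, and so no siMLX library, 3821 of 12808 genes were called, against 3532 of 13001 with the siMLX libraries. That fit kept 95.4% of the 3532 calls. How far siMLX replicate 2 alone widened the spread was not tested. In the authors' deposited table the adjusted p was 2.8e-97 for CHAC1 and 2.59e-26 for TXNIP.

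The second comparison, siMLX against siControl, asks the same of the siRNA against the partner, with the same limit. Fewer genes were called: 484 rose and 610 fell of 13001 tested, 164 and 210 of them at least 2-fold, and 1815 were called with the replicate number as a block. The lysosomal cysteine protease CTSZ fell from 219 ± 18.9 to 32.8 ± 8.14 CPM (-2.74 ± 0.17, edgeR adjusted p = 6.61e-05), and RASD1, a small GTPase, rose from 1.21 ± 0.223 to 20.6 ± 3.75 CPM (4.09 ± 0.23, 4.71e-05). PCK1, nearly lost after siMondoA, stood at 110.3 ± 42.8 CPM against 105 ± 37.6 CPM in siControl (0.08 ± 0.37, edgeR adjusted p = 0.924).

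TXNIP and ARRDC4 differed between the siMLX libraries: TXNIP was at 172, 511 and 93.3 CPM in replicates 1, 2 and 3, against 696 ± 153 CPM in siControl (-1.43 ± 0.59, edgeR adjusted p = 0.154). With the replicate block the TXNIP value was -1.78 ± 0.31 (edgeR adjusted p = 0.00748), and without siMLX replicate 2 it was -2.39 ± 0.49 (0.0198). For ARRDC4 the same 3 fits gave -1.28 ± 0.45 (edgeR adjusted p = 0.102), -1.48 ± 0.28 (0.00992) and -2.1 ± 0.32 (0.00586). HBP1 fell in all 3 fits (-1.22 ± 0.17, edgeR adjusted p = 0.00371), the only 1 of 18 listed MondoA and ChREBP targets called in the fit of all siMLX libraries with no block (camera adjusted p = 0.251), where 3 fell and 1 rose with the block. MXD4 fell by -0.88 ± 0.20 (edgeR adjusted p = 0.0267). MYC was at 637 ± 82.5 CPM against 635 ± 55.5 CPM in siControl (0.00 ± 0.12, 0.986), and HK2, ODC1 and BBC3 did not pass (0.11 ± 0.13, 0.34 ± 0.18 and 1.02 ± 0.45; edgeR adjusted p 0.651, 0.258 and 0.179).

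The stress response genes stood high in siMLX replicate 2 alone. The median of the 43 listed ISR genes above the siControl mean was 0.09, 2.04 and 0.15 in replicates 1, 2 and 3, and CHAC1 was at 0.707, 102 and 1.83 CPM. Over the 3 libraries the list had a camera adjusted p of 0.000197 (adjusted p = 0.801 with an estimated correlation), which was 0.515 without siMLX replicate 2. Of its members CEBPB rose (0.79 ± 0.21, edgeR adjusted p = 0.0482), none passed adjusted over the list alone, and 11 rose with the replicate block. That block was also set by the siMondoA libraries, where replicate 2 stood highest in this list too (2.68, against 1.19 and 1.96). The 11 rises therefore need not show an effect in siMLX replicates 1 and 3. ATF4 was at 0.70 ± 0.28 (edgeR adjusted p = 0.139; with the block 0.62 ± 0.15, 0.0288). ASNS at 2.61 ± 1.03, DDIT3 at 2.34 ± 0.79, TRIB3 at 2.62 ± 0.86, PSAT1 at 1.34 ± 0.60 and SESN2 at 1.15 ± 0.74 did not pass (edgeR adjusted p 0.137, 0.0932, 0.0868, 0.192 and 0.364). Without siMLX replicate 2, ASNS was at -0.09 ± 0.54 and SESN2 fell by -0.93 ± 0.24 (edgeR adjusted p 0.939 and 0.0428). Of 17 immediate early genes 2 rose (5 adjusted over the list alone), JUN (1.71 ± 0.39, edgeR adjusted p = 0.0267) and FOSB (1.01 ± 0.21, 0.0185). That list's camera adjusted p was 0.00527, but 0.201 without siMLX replicate 2 and adjusted p = 0.801 with an estimated correlation. CDKN1A, which encodes the cell cycle inhibitor p21, was at 0.66 ± 0.41 (edgeR adjusted p = 0.337).

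Other lists passed in the fit of all 3 siMLX libraries. Of 28 mitotic genes 7 rose (13 adjusted over the list alone, median 0.41), with CENPA at 1.04 ± 0.14, AURKA at 0.64 ± 0.11 and TPX2 at 0.62 ± 0.12 (edgeR adjusted p 0.0031, 0.00968 and 0.015). The camera adjusted p was 3.77e-07 (adjusted p = 0.771 with an estimated correlation), and 12 rose without siMLX replicate 2 and 11 with the block. Of 23 interferon response genes 5 fell and 1 rose (8 and 2 with the block, 9 and 2 adjusted over the list alone; camera adjusted p = 0.000197, but adjusted p = 0.771 with an estimated correlation), among them IFIT2 (-2.49 ± 0.29), IFIT3 (-1.23 ± 0.21) and the viral tether BST2 (-0.95 ± 0.16; edgeR adjusted p 0.00138, 0.00784 and 0.00821). Of 28 autophagy and lysosome genes 5 fell, including the lysosomal enzymes HEXA (-0.55 ± 0.12) and CTSB (-0.61 ± 0.14; edgeR adjusted p 0.0202 and 0.0294). That list's camera adjusted p of 0.0268 became 0.0857 without siControl replicate 1, 0.0576 without siMLX replicate 1 and 0.0661 without siMLX replicate 3 (adjusted p = 0.771 with an estimated correlation). Of 40 nucleolar MYC targets 1 rose (6 with the block, 0 adjusted over the list alone), LYAR (0.46 ± 0.12, edgeR adjusted p = 0.0424, but 0.0773 to 0.158 without any library but siMLX replicate 1), with a camera adjusted p of 0.000945 (adjusted p = 0.771 with an estimated correlation).

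Genes of the cholesterol synthesis list were higher after siMLX in part. The sterol carrier STARD4 rose by 0.74 ± 0.17 (edgeR adjusted p = 0.0304), 1 of 2 rises among 25 listed genes (camera adjusted p = 0.0682, with the replicate block 0.0308 and 3 rises and 1 fall). Without siMLX replicate 2, 9 rose (14 adjusted over the list alone; camera adjusted p = 4.37e-06, but adjusted p = 0.742 with an estimated correlation). HMGCS1 went from 1.07 ± 0.48 (edgeR adjusted p = 0.191) to 1.5 ± 0.30 (0.0175) in that fit. With at least 4 CPM over the libraries compared and no overlap between the groups, the largest rises were those of TNFAIP6, a hyaluronan-binding protein (4.13 ± 0.69), RASD1, IL1A (3.26 ± 0.87), IL11 (3.22 ± 0.83), the chemokine CXCL3 (3.12 ± 0.83), RELN (3.09 ± 0.82), PRND (2.94 ± 0.38) and IL6 (2.93 ± 0.75). IL11, CXCL3 and RELN stood highest in siMLX replicate 2, at 279, 47.2 and 15.6 CPM, against at most 43.1, 8.92 and 4.57 CPM in the other siMLX libraries. By the same limits the largest falls were those of PTGS1 (-3.26 ± 0.26), the dynein chain DNAH2 (-3.03 ± 0.35), CTSZ, MLX, IFIT2, COL1A2 (-2.43 ± 0.50), CST4 (-2.39 ± 0.40) and ITGA10 (-2.38 ± 0.26). The hepatocyte nuclear factor HNF4A rose from 9.51 ± 1.34 to 50.5 ± 25.6 CPM (2.41 ± 0.48, edgeR adjusted p = 0.0152, but 0.0554 to 0.0781 without any siControl library or siMLX replicate 3) and DMBT1 fell by -1.89 ± 0.21 (0.00118).

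Of 49 genes named for siMLX 32 were called. Genes called in all numbered 254, 301 and 496 without siControl replicates 1, 2 and 3 and 412 without siMLX replicate 3. Of the 32 named calls 15 were made without each library in turn, and the rest were lost at edgeR adjusted p values up to 0.158 without siControl replicate 1 (16 genes), 2 (17) or 3 (13) or siMLX replicate 1 (3), 2 (6) or 3 (11). They were MXD4, CEBPB, IL1A, IL11, CXCL3, RELN, IL6, COL1A2, AURKA, TPX2, HEXA, CTSB, STARD4, LYAR, JUN, FOSB and HNF4A.

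**Figure D3:**
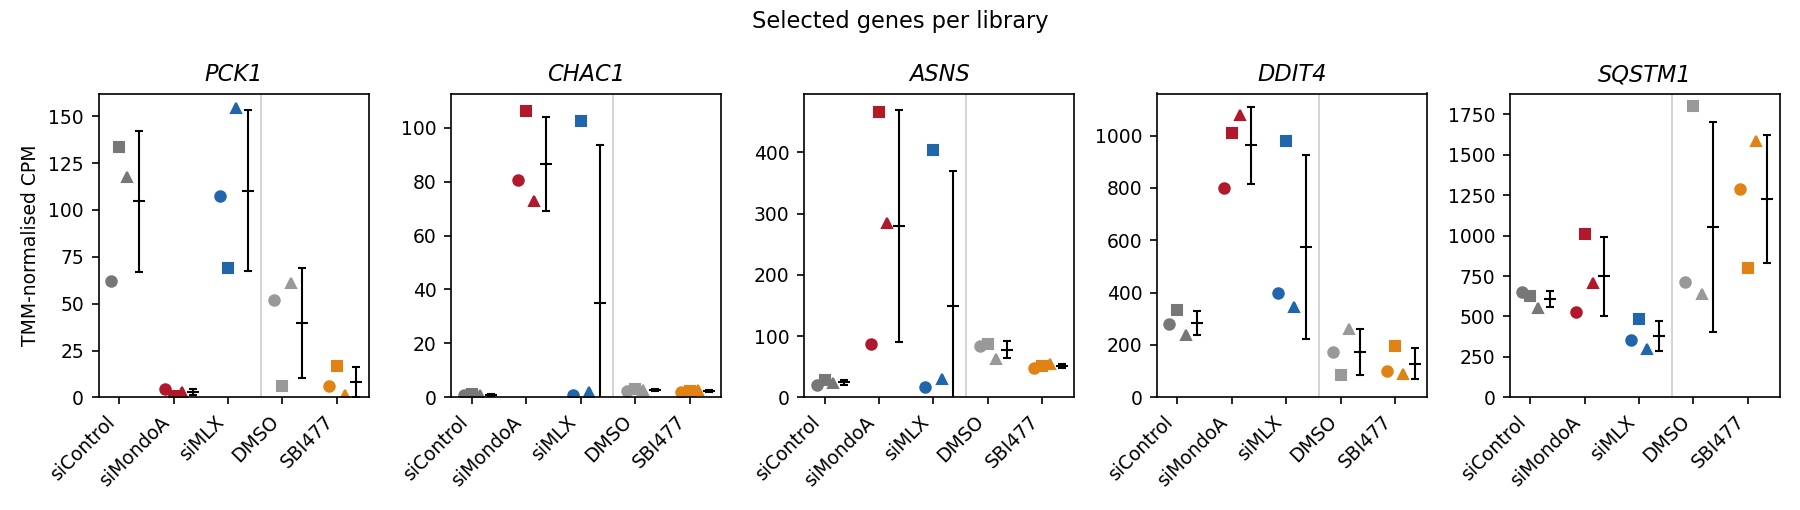
Normalised expression in CPM (vertical axis) of PCK1, CHAC1, ASNS, DDIT4 and SQSTM1 in each library of the 5 groups, with marker shape giving the replicate number and bars giving the mean ± SD of 3 libraries. PCK1 averages 2.63 ± 1.63 CPM in siMondoA and 110.3 ± 42.8 CPM in siMLX, and CHAC1 reaches 102 CPM in siMLX replicate 2 alone of the siMLX libraries.

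Both knockdowns moved many genes the same way. Of 13001 genes tested in both, 301 rose in both and 315 fell in both, where independent calls would give 68.83 and 78.97, and 16 went in opposite directions. The log2 fold changes had a Pearson correlation of 0.665 across genes, which are not independent replicates, and a covariance of 0.253. In 100 simulations of unchanged groups and controls the medians were a correlation of 0.497, a covariance of 0.037 and an overlap of 0 genes, a covariance difference of 0.216. These simulations hold no structure by replicate number, whose effect on such values was not tested. The 3 controls are too few for 2 parts of 2 libraries, so part of the excess may come from them. Without siMLX replicate 2 the counts were 191, 239 and 24, with a correlation of 0.459 and a covariance of 0.164. Genes passing most clearly in both were COBLL1 (1.95 after siMondoA and 1.49 after siMLX), RASD1, the deiodinase DIO2 (2.59 and 2.18) and S100A8 upward, and PTGS1, DMBT1, TRABD2B (-2.53 and -2.17) and ITGA10 downward.

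Tested directly against each other, siMondoA and siMLX differed in 1673 genes, 866 higher and 807 lower in siMondoA. PCK1 differed by -5.38 ± 0.49 (edgeR adjusted p = 0.000349), the epithelial cadherin CDH1 by 3.58 ± 0.40 (0.000913) and BIRC3 by 3.25 ± 0.27 (0.000274). BIRC3 was at 41.5 ± 10.7 CPM in siMondoA and 4.35 ± 1.18 CPM in siMLX, on either side of 9.34 ± 2.12 CPM in siControl. The neuropeptide precursor NTS was at 1830 ± 745 CPM in siMondoA and 8728 ± 708 CPM in siMLX (-2.25 ± 0.30, edgeR adjusted p = 0.00205), and IGFBP5 differed by -2.55 ± 0.20 (0.000179). Not passing were TXNIP (-0.80 ± 0.58), ARRDC4 (-0.80 ± 0.46), MYC (-0.38 ± 0.12), ATF4 (0.59 ± 0.28), CHAC1 (1.30 ± 1.11) and SESN2 (2.29 ± 0.72; edgeR adjusted p 0.376, 0.269, 0.0585, 0.18, 0.457 and 0.0611). Without siMLX replicate 2 the values of TXNIP and ARRDC4 were 0.16 and 0.02.

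By list, 17 of 71 ribosomal protein genes were lower after siMondoA than after siMLX (40 adjusted over the list alone; camera adjusted p = 3.22e-12, but adjusted p = 0.653 with an estimated correlation), with RPL11 at -0.70 ± 0.12 and RPL34 at -0.73 ± 0.13 (edgeR adjusted p 0.00614 and 0.0062). In NF-kB targets 7 of 16 were higher (10 adjusted over the list alone; camera adjusted p = 2.37e-06, but adjusted p = 0.653 with an estimated correlation), including CCL20 (2.97 ± 0.78), NFKB2 (1.39 ± 0.31) and the inhibitor NFKBIA (0.62 ± 0.12). Of 25 cholesterol genes 8 were lower and 1 higher (12 and 1 adjusted over the list alone; camera adjusted p = 0.00186, but adjusted p = 0.735 with an estimated correlation), with HMGCS1 at -1.75 ± 0.49 (edgeR adjusted p = 0.0424, but 0.126 to 0.143 without siMondoA replicate 2 or 3 or siMLX replicate 1 or 3). Of 21 unfolded protein response genes 7 were higher (10 adjusted over the list alone; camera adjusted p = 0.00186, but adjusted p = 0.653 with an estimated correlation): the sensor ERN1 by 1.63 ± 0.36, the chaperones HYOU1 by 0.70 ± 0.16 and HSP90B1 by 0.53 ± 0.13. Of 28 autophagy and lysosome genes 3 were higher (camera adjusted p = 0.00186, but adjusted p = 0.653 with an estimated correlation), among them cathepsin CTSD (0.95 ± 0.16) and the autophagy receptor SQSTM1 (0.99 ± 0.23). The ISR list was higher (camera adjusted p = 2.97e-07, but adjusted p = 0.727 with an estimated correlation) with 2 of 43 members called, 1 of them VEGFA (1.53 ± 0.44), and 39 called without siMLX replicate 2. Weaker were immediate early genes (1 of 17, camera adjusted p = 0.0115; 0.0678 without siMLX replicate 1 and 0.0771 without siMLX replicate 3) and mesenchymal and basal genes (1 of 14, 0.0292; 0.0938 without siMLX replicate 3), at an adjusted p = 0.735 and 0.653 with an estimated correlation. Weaker still were the 19 purine and pyrimidine genes, lower in siMondoA with 0 called (camera adjusted p = 0.0411, 0.0514 with only the 6 libraries compared, or 0.123 and 0.0818 without siMondoA replicates 2 and 3 and 0.224 without siMLX replicate 3; adjusted p = 0.653 with an estimated correlation).

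By fold, under the same limits, MLX, CDH1, BIRC3, CCL20, C15orf48 (3.10 ± 0.64) and the connexin GJB2 (2.89 ± 0.58) led the genes higher in siMondoA, with SERPINB2 and OLR1 at 0.131 and 0.349 CPM in siMLX. PCK1, PXYLP1 (-2.60 ± 0.24), IGFBP5, the proteoglycan DCN (-2.51 ± 0.36), ZNF488 (-2.27 ± 0.55), MLC1 (-2.27 ± 0.42), NTS and SUSD2 (-2.17 ± 0.26) led those lower. Of 43 genes named here 31 were called. In all 706 genes were called with only the 6 libraries compared, 994 and 751 without siMondoA replicates 2 and 3, and 734, 2970 and 670 without siMLX replicates 1, 2 and 3. Of the 31 named calls 15 were made without each library in turn. The remaining ones were lost without siMondoA replicate 2 (12 genes) or 3 (12) or siMLX replicate 1 (14) or 3 (13), at edgeR adjusted p values up to 0.147. These genes were HK2, HMGCS1, CDKN1A, VEGFA, NFKB2, NFKBIA, CCL20, ERN1, HYOU1, HSP90B1, SQSTM1, HNF4A, LDHA, C15orf48, GJB2 and ZNF488.

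The third comparison, SBI-477 against DMSO, asks which transcripts respond to the inhibitor. As labelled, edgeR called 0 of 14023 genes; 409 had an unadjusted p under 0.05, and DESeq2 and limma-voom also called 0. The library labelled replicate 2 ran opposite to replicates 1 and 3 in both groups. TXNIP was at 145, 39.2 and 204 CPM in the libraries labelled DMSO 1, 2 and 3 and at 74.6, 121 and 41.5 CPM in those labelled SBI-477 (-0.71 ± 0.57, edgeR adjusted p = 1). PCK1 was at 51.9, 6.26 and 61.1 CPM against 6.16, 16.8 and 1.15 CPM. ARRDC4 (-0.64 ± 0.40), MLXIP (-0.09 ± 0.11), MLX (0.28 ± 0.10), MYC (-0.03 ± 0.15), ATF4 (-0.37 ± 0.11), ASNS (-0.60 ± 0.15) and TRIB3 (-0.42 ± 0.12) had an edgeR adjusted p of 1 each.

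The authors' deposited table for this drug comparison was not computed with those labels. Its fold changes were matched by DESeq2 with the labels of DMSO replicate 2 and SBI-477 replicate 2 exchanged, with a median absolute difference of 1.89e-07 over 13086 genes. With the labels as given the correlation with that table was 0.2825, or 0.5279 with a replicate term. The authors' deposited table called 2941 genes, 1547 higher and 1394 lower, and held TXNIP at -1.59, ARRDC4 at -1.16 and PCK1 at -3.24. No record in the deposited data settles which labels are right, although the counts argue against those given for replicate 2, as set out below. The comparison is therefore given as labelled and, chosen after seeing the data, for the 4 libraries of replicates 1 and 3, whose labels both sources share.

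In those 4 libraries 1291 genes rose and 1284 fell of 14232 tested, 117 and 355 at least 2-fold. With library totals in place of TMM 790 rose and 1828 fell, a median shift of -0.088. TXNIP fell by -1.58 ± 0.24, ARRDC4 by -1.31 ± 0.20, ARRDC3 by -0.80 ± 0.15, HBP1 by -0.81 ± 0.15 and MLXIPL by -1.95 ± 0.24 (edgeR adjusted p 0.00389, 0.00391, 0.00773, 0.00898 and 0.00178). PCK1 fell by -3.87 ± 0.40 (edgeR adjusted p = 0.000906), from 51.9 and 61.1 CPM to 6.16 and 1.15 CPM. Of 5 arrestin domain genes 4 fell (camera adjusted p = 0.0358, but adjusted p = 0.777 with an estimated correlation) and of 18 MondoA and ChREBP targets 7 fell and none rose (3 rose and 7 fell adjusted over the list alone; camera adjusted p = 0.231). MLXIP (-0.20 ± 0.09) and MYC (-0.22 ± 0.11) did not pass, MLX rose by 0.29 ± 0.09, and of the MYC antagonists MXI1 fell by -0.61 ± 0.09 and MXD1 rose by 0.52 ± 0.13 (edgeR adjusted p 0.128, 0.183, 0.0457, 0.00342 and 0.0227).

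The ISR list did not rise here: 5 of 42 members rose and 8 fell (5 and 10 adjusted over the list alone; camera adjusted p = 0.44). ATF4 fell by -0.43 ± 0.09, ASNS by -0.50 ± 0.14, TRIB3 by -0.40 ± 0.11 and DDIT4 by -1.19 ± 0.16, and ATF5 rose by 0.96 ± 0.13 (edgeR adjusted p 0.0105, 0.0349, 0.0345, 0.00236 and 0.00229). In the authors' deposited table ATF4 (-0.17), ASNS (-0.04) and TRIB3 (-0.08) were not called (authors' adjusted p 0.455, 0.956 and 0.783). DDIT4 (-1.19) and ATF5 (0.94) were called there. CHAC1 (-0.10 ± 0.28), DDIT3 (0.07 ± 0.15), SESN2 (-0.03 ± 0.15) and PSAT1 (-0.01 ± 0.11) did not pass. Of 28 autophagy and lysosome genes 11 rose and 3 fell (camera adjusted p = 0.00385, but adjusted p = 0.777 with an estimated correlation), with SQSTM1 at 1.09 ± 0.12 and the proton pump subunit ATP6V0D1 at 0.73 ± 0.09 (edgeR adjusted p 0.000915 and 0.0017). Of 25 cholesterol genes 9 fell and 3 rose (11 and 3 adjusted over the list alone; camera adjusted p = 0.0157, but adjusted p = 0.777 with an estimated correlation), including STARD4 (-1.20 ± 0.10), the sterol sensor partner INSIG1 (-1.44 ± 0.12), the regulator SREBF2 (-0.73 ± 0.11) and HMGCS1 (-0.71 ± 0.13). Of 18 hypoxia genes 9 fell and 2 rose (11 and 2 adjusted over the list alone; camera adjusted p = 0.00386, but adjusted p = 0.777 with an estimated correlation), with carbonic anhydrase CA9 at -2.0 ± 0.23, PDK1 at -0.88 ± 0.10, BNIP3L at -0.89 ± 0.11 and, upward, ANGPTL4 at 1.33 ± 0.13.

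Rises in the same 4 libraries were 9 of 40 nucleolar MYC targets (13 adjusted over the list alone; camera adjusted p = 0.000282), such as ODC1 (0.70 ± 0.13), spermidine synthase SRM (0.64 ± 0.13) and RRS1 (0.59 ± 0.13), and 9 of 28 DNA replication genes (10; 0.00216), such as cyclin CCNE1 (0.81 ± 0.09) and the licensing factor CDC6 (0.71 ± 0.13). Both lists had an adjusted p = 0.777 with an estimated correlation, as did the 3 that follow. Of 28 mitotic genes 8 rose (10 adjusted over the list alone; camera adjusted p = 0.0188), with FOXM1 at 0.43 ± 0.10 and CCNA2 at 0.43 ± 0.10, and of 40 oxidative phosphorylation genes 4 rose (2; 0.00385), with NDUFB10 at 0.54 ± 0.10. Of 7 fibroblast markers 4 fell and 1 rose (6 and 1 adjusted over the list alone; camera adjusted p = 0.0452), led by COL1A1 (-2.37 ± 0.25) and COL1A2 (-2.67 ± 0.43). Under the limits used above the steepest rises were HSD11B1, which activates cortisol (3.33 ± 0.23), the BMP antagonist GREM1 (2.38 ± 0.14), PI3 (2.36 ± 0.27), UGT1A7 (1.94 ± 0.14; its exons are shared with related genes), SCG5 (1.93 ± 0.27), RPPH1 (1.91 ± 0.30), SPP1 (1.78 ± 0.30) and CXCL3 (1.73 ± 0.22). The steepest falls were PCK1, the acute phase genes SERPINA3 (-3.27 ± 0.30), LCN2 (-3.06 ± 0.16), FGG (-2.84 ± 0.51) and FGB (-2.68 ± 0.43), then DMBT1 (-3.14 ± 0.29), RARRES1 (-2.94 ± 0.37) and COL1A2. CDKN1A rose by 1.09 ± 0.20, BBC3 fell by -0.80 ± 0.16 and HK2 did not pass (0.22 ± 0.08; edgeR adjusted p 0.00754, 0.0113 and 0.0864).

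Of 59 genes named for these 4 libraries 52 were called. Among these, MLX (0.13), FOXM1 (0.22) and RPPH1 (1.05) were also not called in the authors' deposited table (authors' adjusted p 0.549, 0.26 and 0.235). Leaving out 1 of these libraries leaves 1 library in its group, so the other group alone gives the spread. Such fits cannot show that a call is stable. Calls of MLX, MXD1, FOXM1, ASNS, TRIB3 and CCNA2 were not made in all of them. Nor were those of the nucleolar, DNA replication, mitosis, cholesterol, oxidative phosphorylation, arrestin and fibroblast lists.

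**Figure D4:**
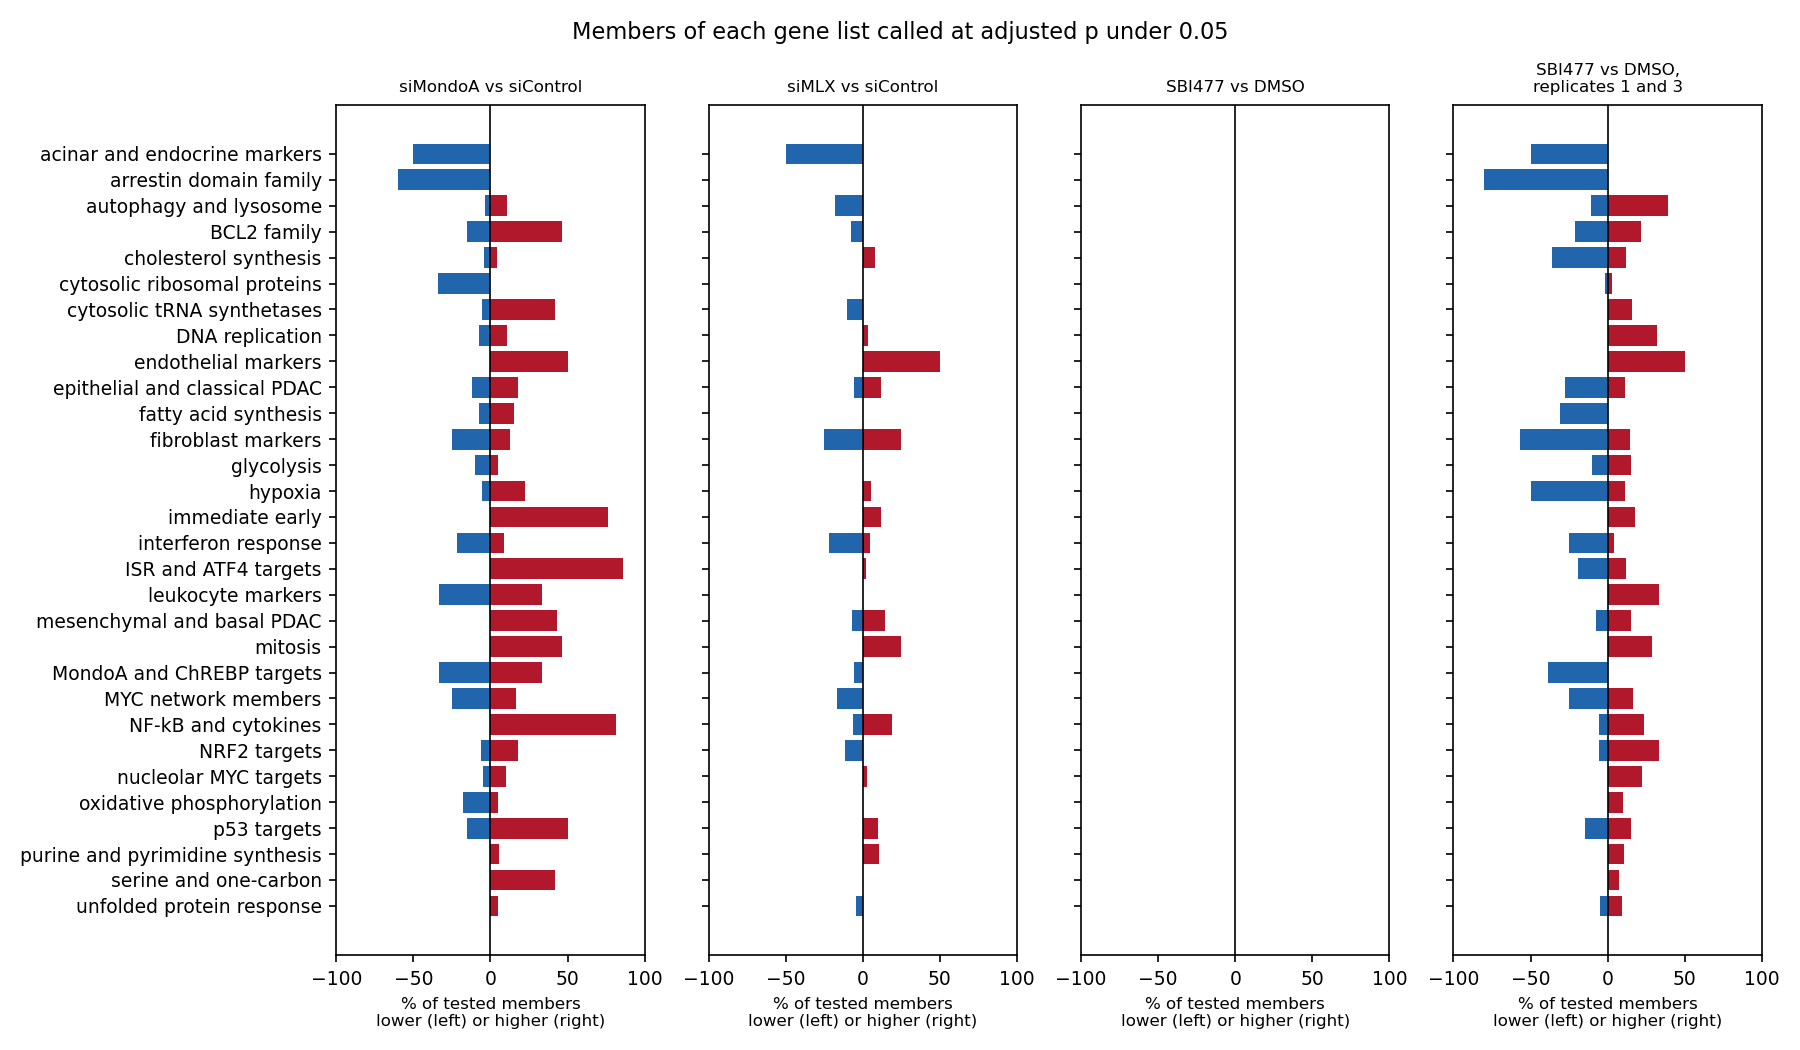
Percentage of the tested members of each gene list called lower (left of 0) and higher (right of 0), in panels for siMondoA, siMLX, SBI-477 as labelled and SBI-477 in replicates 1 and 3. The panel for SBI-477 as labelled is empty because 0 genes were called there. In the ISR list 37 of 43 members were called higher after siMondoA and 1 of 43 after siMLX.

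The last comparison sets the inhibitor beside the knockdown of its stated target. With all labels as given, the effects of SBI-477 and siMondoA differed in 1049 of 13681 genes, 525 with the drug effect above and 524 below. CHAC1 differed by -6.69 ± 1.72 (edgeR adjusted p = 0.0304), ATF4 by -1.64 ± 0.34 (0.0125), DDIT3 by -3.72 ± 0.91 (0.0255) and CCL20 by -6.96 ± 1.40 (0.0114), all with the drug effect below that of siMondoA, and MLXIP by 1.88 ± 0.21 (0.000571). The smallest adjusted p belonged to the coagulation factor receptor F3 (-2.39, edgeR adjusted p = 0.000132). TXNIP (1.54 ± 0.89), ARRDC4 (1.46 ± 0.66) and PCK1 (3.02 ± 1.15) did not pass (edgeR adjusted p 0.299, 0.181 and 0.114). A drug effect below that of siMondoA need not be a fall: mitotic genes rose with the drug in replicates 1 and 3. By list, the drug effect lay below that of siMondoA for ISR genes (camera adjusted p = 2.1e-16), NF-kB targets (1.98e-08), immediate early genes (2.21e-06), mitotic genes (0.00263) and mesenchymal genes (0.0386). None of these calls held with an estimated correlation (adjusted p = 0.832 for mitotic genes and 0.701 for the others). Over the 4 drug libraries of replicates 1 and 3 the effects differed in 1595 genes and the ISR list had a camera adjusted p of 1.45e-10 (adjusted p = 0.848 with an estimated correlation). In that fit ATF4 differed by -1.69 ± 0.39 (edgeR adjusted p = 0.021), while CHAC1 (-6.59 ± 2.1), TXNIP (0.67 ± 0.86), ARRDC4 (0.79 ± 0.66) and PCK1 (1.43 ± 0.82) did not pass (0.0587, 0.633, 0.447 and 0.26). The mesenchymal list lost its call there (camera adjusted p = 0.0631). Ribosomal protein (2.37e-09) and oxidative phosphorylation genes (4.27e-05) gained one, with the drug effect above that of siMondoA, and hypoxia genes (0.00476) with it below. With an estimated correlation these 3 lists had an adjusted p = 0.848. The gene count with all labels was 429, 464 and 540 without siControl replicates 1, 2 and 3, 1680, 476 and 461 without siMondoA replicates 1, 2 and 3, 453 without DMSO replicate 1, and 423 and 435 without SBI-477 replicates 1 and 3.

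Genes set by siMondoA were followed in the drug libraries. As labelled, no gene was called in both; the 181 genes lowest after siMondoA had a median of -0.22 (camera adjusted p = 0.015 over the 2 sets, but adjusted p = 0.897 with an estimated correlation). That value was 0.147 with the opposite sign without DMSO replicate 3, and 0.21 without SBI-477 replicate 3. The 175 genes highest after siMondoA had a median of -0.04 (camera adjusted p = 0.755). In replicates 1 and 3, 57 of 186 such lower genes fell and 6 rose (camera adjusted p = 9.82e-07, but adjusted p = 0.401 with an estimated correlation), and 40 of 179 higher genes rose and 16 fell (camera adjusted p = 0.00762, but adjusted p = 0.1 with an estimated correlation). Over all calls 272 genes rose in both and 290 fell in both, where independent calls would give 178.4 and 157.5, while 243 moved in opposite directions. The number of opposite moves that independent calls would give was not computed, so the 243 alone do not measure disagreement. Among the shared genes WLS (1.45 after siMondoA and 1.23 with the drug) and SEMA7A (1.47 and 0.95) rose, and PCK1, DMBT1 and the LIF receptor LIFR (-1.45 and -1.0) fell.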

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

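Chosen after the result was seen were the test of exchanged labels, the 3 tests on siMLX replicate 2, the splits of the drug gene counts and the spread put on the genes matched to ribosomal protein genes.

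The drug libraries labelled replicate 2 stood apart in both groups. Both of them, 2 of 2, correlated better with replicates 1 and 3 of the other group than with those of their own label (0.9872 against 0.9753 for DMSO replicate 2 and 0.9922 against 0.9847 for SBI-477 replicate 2). Unequal depth does not account for it: with each drug library thinned to 23315440 counts edgeR called 0 genes as labelled, with 414 at an unadjusted p under 0.05, and 2465 with the labels exchanged (2484 without thinning). An exchange of labels between this pair of libraries would put both nearer to their group and give the authors' deposited table. DMSO replicate 2 would still stand somewhat apart. Its Spearman correlations with SBI-477 replicates 1 and 3 were 0.99 and 0.991, against 0.997 between those 2 libraries. SBI-477 replicate 2 was at 0.996 and 0.994 with DMSO replicates 1 and 3, against 0.995 between them. An error in that table alone, with the labels right, would leave both libraries nearest to their own group. The correlations and gene counts above argue against that for these 2 libraries. No record of the samples was at hand to settle it. A drug response that varied between cultures would leave DMSO replicate 2 in place, yet TXNIP was at 39.2 CPM there against 145 and 204 CPM in DMSO replicates 1 and 3.

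In siMLX replicate 2 the integrated stress response genes stood at 2.04 above the siControl mean, against 0.09 and 0.15 in the other siMLX libraries. Weaker knockdown is argued against by MLX at 7.15 CPM there, below the 15.2 CPM that such an explanation needs at least. A mixture with siMondoA material is argued against by MLXIP at 66.6 CPM, where the share read from the stress genes predicts 20.5 CPM and the SD of siControl is 12. A condition common to all replicate 2 libraries is argued against by a shift of 0.08 in siControl replicate 2, against 1.79 in siMLX replicate 2. siMondoA replicate 2 was also the highest of its group (2.68 against 1.19 and 1.96), so a condition shared by only the knockdown libraries of replicate 2 may have contributed, which was not tested, and how far MLX loss itself moves these genes stays open.

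Ribosomal protein transcripts were lower after siMondoA by a median of -0.29 over 71 genes. By library, siControl replicate 3 (-0.16 from the siControl mean) was level with siMondoA replicate 2 (-0.17). Scaling does not account for the lower median over 71 genes, since it was -0.30 with DESeq2 size factors and -0.33 with library totals. A trend with transcript length or expression level could not be settled: 121 genes matched on both had a median of -0.10, with a bootstrap interval of -0.17 to 0.06 over 2000 resamples that holds -0.144, the bound set beforehand. A lower output of ribosomal protein genes after loss of MondoA may be considered as a hypothesis only, and was not tested further.

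The counts of genes called were compared with other splits of the same libraries. For each comparison of 3 against 3 libraries the 10 splits are too few for a share under 0.05. The real value and the highest of the other splits were 3532 and 0 genes for siMondoA, 1094 and 0 for siMLX and 1673 and 1213 for siMondoA against siMLX, each with 1 split as large, the real one. The split with 1213 genes put siMondoA replicate 1 with siMLX replicates 1 and 3, and points to a structure of the samples that crosses the groups. For SBI-477 they were 0 and 2484 genes, all 10 splits being as large, and the split with 2484 is the one with replicate 2 exchanged, which likewise points to a structure of the samples. For lists past the threshold the values were 6 and 10 for siMondoA (7 splits as large), 6 and 15 for siMLX (8), 9 and 14 for siMondoA against siMLX (6) and 7 and 12 for SBI-477 (6). For the siMondoA gene sets in the drug libraries the camera adjusted p was 0.755 against 5.54e-05 as the lowest other for the higher set (10 splits as small) and 0.015 against 9.2e-11 for the lower set (8). Of 100 splits within the experiments 9, the real one included, reached the count of 1049 genes whose SBI-477 and siMondoA effects differ. The median of the other splits was 0 genes and the highest 2055. Labels were drawn separately in each experiment, so a split can keep siMondoA and siControl apart and still hold that effect. These splits therefore cannot decide on chance, which is not excluded for that count.

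Effects that differed by a test of the difference itself were 1049 genes between SBI-477 and siMondoA and 1673 genes between siMondoA and siMLX. On the log2 scale, the named genes with a higher effect of siMondoA than of siMLX were CDH1 (3.58), BIRC3 (3.25), C15orf48 (3.10), MLX (3.0), CCL20 (2.97), GJB2 (2.89), CDKN1A (1.68), ERN1 (1.63), VEGFA (1.53), NFKB2 (1.39), SQSTM1 (0.99), CTSD (0.95), HYOU1 (0.70), NFKBIA (0.62), HSP90B1 (0.53) and HK2 (0.51). Those with a lower effect were PCK1 (-5.38), PXYLP1 (-2.60), IGFBP5 (-2.55), DCN (-2.51), MLC1 (-2.27), ZNF488 (-2.27), NTS (-2.25), SUSD2 (-2.17), HMGCS1 (-1.75), HNF4A (-1.74), MLXIP (-1.68), LDHA (-0.98), BCL2L11 (-0.97), RPL34 (-0.73) and RPL11 (-0.70).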

How the results depend on the processing

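Chosen after the data were seen were the settings with only the drug libraries of replicates 1 and 3, with the labels of drug replicate 2 exchanged, the lists with only the 6 libraries compared, the overlaps without siMLX replicate 2, all settings varied within replicates 1 and 3, left-out libraries for the difference of effects, and size factors, the block and left-out libraries for the gene sets. With the other scaling, filter and test settings each count of called genes and of lists stayed within 1.5 times its value, except as follows; the cause was not tested unless named. Lists past the threshold numbered 0 with an estimated correlation in each comparison, and by fry 1 for siMLX, 0 for siMondoA against siMLX, 0 for SBI-477 and 2 for SBI-477 in replicates 1 and 3, none of these passed by camera. The MondoA and ChREBP target list was lower by fry after siMLX (adjusted p = 0.0369) and in replicates 1 and 3 (0.0499), where immediate early genes were higher (0.0499). For siMondoA fry passed 4: it dropped ISR, ribosomal, immediate early and mesenchymal genes (adjusted p = 0.0524) and mitosis (0.0564), and added MondoA and ChREBP targets (0.0151), the MYC network and p53 targets. With only the 6 libraries compared siMondoA against siMLX called 706 genes, a fit with fewer libraries. The replicate block called 1815 genes for siMLX, and 2606 for siMondoA against siMLX. In the latter, deviations of replicates 1, 2 and 3 correlated at 0.53, 0.45 and -0.11. Replicates 1 and 2 correlated best with their own number and replicate 3 did not, so whether the numbers pair these groups is open. Beside the siMLX calls given with the block in the report, the block brought the list of acinar and endocrine markers to a camera adjusted p of 0.0308. Only 2 genes of that list were tested, both lower, and the block was not run with an estimated correlation. No other call of a named gene or list changed in that comparison. Same-numbered deviations were 0.14, 0.09 and 0.01 for siMondoA and siControl (replicate block 4551 genes) and -0.24, -0.56 and -0.45 for the drug libraries (0 genes).

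For SBI-477, 2575 genes were called in replicates 1 and 3 and 2484 with the labels exchanged. The ribosomal list turned in direction to a camera adjusted p of 0.14 and 8.08e-05 in these settings (the latter with an adjusted p = 0.666 with an estimated correlation), and the ISR list to 0.607 with the labels exchanged. The difference between SBI-477 and siMondoA effects counted 1595 and 2988 genes. The lower siMondoA set went to an adjusted p = 0.897 with an estimated correlation, 0.804 by fry, and with an estimated correlation to 0.401 in replicates 1 and 3 and 0.226 with exchanged labels. The higher set turned upward at an adjusted p = 0.04 with all genes called, 0.00762 in replicates 1 and 3 (0.1 with an estimated correlation) and 7.89e-05 with exchanged labels (0.0402). Overlaps in the same direction were 115 genes for siMondoA and siMLX at an adjusted p under 0.01, a stricter threshold, and 562 for siMondoA and SBI-477 in replicates 1 and 3. MYC after siMLX, near 0 as reported, was at 0.00 under DESeq2 size factors, no filter, DESeq2 and limma-voom, -0.02 with library totals and -0.01 with 6 libraries, and DDIT3 with the drug in replicates 1 and 3 was at -0.01 with library totals.

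Leaving out each library in turn gave 1745 to 3884 genes and 6 to 10 lists for siMondoA, 254 to 833 genes for siMLX, 670 to 2970 genes for siMondoA against siMLX, 4 to 9 lists for SBI-477, and 1194 to 4319 genes and 2 to 14 lists for SBI-477 in replicates 1 and 3, each from fewer samples. The difference of effects ranged from 423 to 1680 genes. The adjusted p of the higher set ranged from 0.0622 to 0.323 and that of the lower set from 5.34e-06 to 0.21. The higher set turned upward without DMSO replicate 2 (0.323) and SBI-477 replicate 2 (0.139), and the lower set without DMSO replicate 3 (0.147). Other values that changed sign were, after siMLX, MYC (-0.11 to 0.08), PCK1 (-0.25 to 0.32), ASNS (-0.09 to 3.14) and SESN2 (-0.93 to 1.63), and, for siMondoA against siMLX, ODC1 (-0.22 to 0.16), TXNIP (-1.27 to 0.16) and ARRDC4 (-1.12 to 0.02). With the drug they were MYC (-0.17 to 0.08) and the ribosomal (2.52e-13 to 0.457) and nucleolar (5.45e-07 to 0.839) lists as labelled. In replicates 1 and 3 they were CHAC1 (-0.43 to 0.21), DDIT3 (-0.13 to 0.29), SESN2 (-0.09 to 0.03) and PSAT1 (-0.13 to 0.12). Over all settings and named genes, 938 of 993 values kept direction and side of the threshold for siMondoA, with 54 weaker (48 of them from a left-out library), 578 of 686 for siMLX with 81 weaker (66), 515 of 602 for siMondoA against siMLX with 66 weaker (51), and 109 of 120 for SBI-477. Replicates 1 and 3 are not counted here, since some of those fits have 1 library in a group. Many genes were named for their fold or adjusted p in these same fits, so such shares need not hold for other genes. Over all genes called, leaving out 1 library kept 48.6% to 87.3% of the siMondoA calls. For siMLX it kept 22.9% to 65.4%, and for siMondoA against siMLX 39.4% to 93.3%. The 8 genes named for SBI-477 as labelled were not called in the fit of all 6 libraries, where 0 genes were. Depth limits the siRNA comparisons to genes above about 0.267 CPM and the drug comparison to those above 0.129 CPM, for counting error only.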

Other observations

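The gene groups described here were fixed in advance, and no test was chosen after its result was seen except where said. Cell death and p53 genes moved in both directions after siMondoA. Of 13 BCL2 family genes 6 rose and 2 fell (camera adjusted p = 0.276): the survival factor MCL1 rose by 1.49 ± 0.32 and the death-promoting PMAIP1 and BBC3 by 2.44 ± 0.59 and 1.49 ± 0.45, while the death-promoting BMF and BCL2L11 fell by -1.41 ± 0.31 and -0.66 ± 0.15 (edgeR adjusted p 0.00885, 0.0142, 0.0323, 0.00949 and 0.0107). Of 20 p53 targets 10 rose and 3 fell (camera adjusted p = 0.174), with CDKN1A at 2.34 ± 0.40, MDM2 at 0.70 ± 0.13 and PHLDA3 at 1.49 ± 0.25 (edgeR adjusted p 0.00337, 0.00454 and 0.00316). PDAC state genes were also mixed: of 17 epithelial and classical genes 3 rose and 2 fell (camera adjusted p = 0.638; median -0.32 and mean 0.09, so the signs differ), with CDH1 at 2.38 ± 0.37 and the classical factor GATA6 at 0.90 ± 0.14 among those that rose (edgeR adjusted p 0.00215 and 0.00228). Of 23 interferon response genes 5 fell and 2 rose (camera adjusted p = 0.0911), IFITM1 by -1.59 ± 0.19 and BST2 by -0.95 ± 0.16 (edgeR adjusted p 0.000736 and 0.00317).

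After siMondoA, of 25 cholesterol genes 1 rose and 1 fell (camera adjusted p = 0.232). Lactate dehydrogenase LDHA fell from 2726 ± 174 to 1347 ± 382 CPM (-1.02 ± 0.23, edgeR adjusted p = 0.0105), 1 of 2 falls against 1 rise among 20 glycolysis genes (camera adjusted p = 0.336). The folate enzyme MTHFD2 rose by 2.19 ± 0.48 (edgeR adjusted p = 0.0101), 1 of 5 rises among 12 serine and one-carbon genes (camera adjusted p = 0.276). Rises and falls were 8 and 1 of 19 cytosolic tRNA synthetases (camera adjusted p = 0.0519), 2 and 1 of 13 fatty acid synthesis genes (0.276), 4 and 1 of 18 hypoxia genes (0.576) and 3 and 1 of 17 NRF2 targets (0.638). They were 4 and 2 of 40 nucleolar MYC targets (camera adjusted p = 0.26), 3 and 2 of 28 DNA replication genes (0.632), and 3 and 1 of 28 autophagy and lysosome genes (0.455), where WIPI1 rose by 1.78 ± 0.37. Single rises were seen among 19 purine and pyrimidine genes (camera adjusted p = 0.382) and 21 unfolded protein response genes (0.26), the latter ERN1 (1.99 ± 0.36).

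Markers of other cell types gave no common direction after siMondoA. Calls were 1 rise and 2 falls of 8 fibroblast markers (camera adjusted p = 0.357), with COL1A2 at -3.91 ± 0.56 and PDGFRB at -1.93 ± 0.24, 1 rise and 1 fall of 3 leukocyte markers (0.638), with CD68 at 1.06 ± 0.16, 1 rise of 2 endothelial markers (0.26), KDR at 0.94 ± 0.22, and 1 fall of 2 acinar and endocrine markers (0.263), CPA1 at -2.80 ± 0.61.

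As labelled, SBI-477 libraries passed 7 lists by camera, each with an adjusted p = 0.972 with an estimated correlation, although edgeR called 0 genes, with 409 at an unadjusted p under 0.05 and 0 by DESeq2 and limma-voom. Ribosomal protein genes were lower (camera adjusted p = 2.46e-05, median -0.17; 0.457 without DMSO replicate 2, with the opposite sign), and ISR genes were lower (0.00148; 0.272 without DMSO replicate 2). DNA replication genes were higher (camera adjusted p = 0.000173; 0.581 without DMSO replicate 3), as were nucleolar MYC targets (0.00425; 0.839 without DMSO replicate 3 with the opposite sign, and 0.131 without SBI-477 replicate 3) and mitotic genes (0.0173; 0.581 without DMSO replicate 3, and 0.105 and 0.0759 without SBI-477 replicates 1 and 3). Hypoxia genes were lower (camera adjusted p = 0.0261; 0.21 and 0.513 without DMSO replicates 1 and 3, and 0.356 without SBI-477 replicate 3), and interferon genes were lower (0.0261; 0.513 without DMSO replicate 3, and 0.163 and 0.0759 without SBI-477 replicates 2 and 3).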
